A study of Mus musculus with 8 samples.

How the data were processed

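The study profiled trimethylated lysine 4 of histone H3 (H3K4me3), a mark of active promoters, by chromatin immunoprecipitation and sequencing in mouse brain at embryonic day 12.5. The labels give 2 groups, wild type (WT) controls without Cre and double knockouts (dKO) of Lats1 and Lats2 with Nestin-Cre, each with 2 H3K4me3 libraries. Another 4 libraries are input chromatin, 2 for each genotype, and were not analysed here. Only the dKO group carried Cre, so an effect of Cre cannot be separated from the loss of Lats1 and Lats2. A genotype effect below covers both. The mice had a mixed strain background. The extraction protocol describes brains handled singly, but no label names the animal behind each library, so p-values measure the spread between these libraries.

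Per the submitters' processing notes, the tools were BWA 0.7.12-r1039, Picard 2.6.0, SAMtools, R 2.14.0, MACS2 2.1.1.20160309 and bedtools, with genome build mm9. The notes used here do not give the role of each tool, its thresholds, or whether input chromatin entered the peak calling. The deposited data are peak lists, 1 per H3K4me3 library, with the position of each peak and a score. The scale of the deposited score is not named by the authors in the labels, and its lowest value was 13 in every list. The score was used only to rank peaks within their own list and to describe each list, and no test was run on it. No list gives read counts, so the sequencing depth is unknown, and no interval for depth could be attached to any peak. A deeper or cleaner library gives more and wider peaks at the same threshold, and this cannot be separated here from a change in the mark.

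Peak positions are given on mm9, counted from 1. The reference table used here is of build GRCm38.p6. As a check, its coordinates were set unconverted against the WT replicate 1 peaks. Of these peaks, 11.5% lay within 1000 bp of a protein-coding gene end. The builds differ, and the table was not used to annotate peaks. For that reason no promoter, gene, exon or intron was assigned to any region, the peaks at Lats1 and Lats2 were not examined as a check of the genotype labels, and the 27 gene lists that had been fixed were not tested. Regions are named by their coordinates.

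Peaks were compared in 3 ways with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and bedtools 2.31.1. The number of peaks, the base pairs under peaks and the median peak width of each library were compared between genotypes by an exact two-sided permutation test. With 2 libraries against 2, that test cannot give a p below 0.3333. The peaks of the 4 lists were then merged into union regions wherever they overlapped by at least 1 bp, and each region was described by the libraries with a peak in it. The counts for the genotypes were set beside those from the 2 other ways of dividing the 4 libraries into pairs.

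For the width of the mark, the base pairs under peaks in each region with a peak in all 4 libraries were converted to log2, centred on the median of each library, and fitted with limma 3.58.1 (R 4.3.3, empirical Bayes with a variance trend). Benjamini-Hochberg adjusted p under 0.05 was the threshold. The fit was tested on simulated data with the same 14943 regions, 200 of them changed, in 5 rounds. It recovered 88% of regions with a log2 change of -2, 42.4% at -1, 66.4% at 1 and 95.6% at 2, and 33 of its 764 calls were false. The simulated noise was independent and normal, with variances drawn from the model fitted to these widths. These values therefore hold under the assumptions of the model and with 200 changed regions. They do not measure error or recovery in the real widths.

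The following rules were set before the data were examined. Named regions are the 10 with the largest width change in each direction past the threshold, or, where none pass, the 5 with the smallest p in that direction, given as values only. They also include the 10 widest regions with a peak only in both libraries of a genotype, by the smaller of the 2 widths, and the 10 widest by mean width over the 4 libraries. Alternatives were lists limited to the 17367 peaks with the highest scores, peaks within 1000 bp merged first, autosomes only, peaks under 500 bp left out, and sharing that required 50% of the shorter peak. For the width fit they were no centring, quantile normalization, the replicate number as a block, no variance trend, and regions in at least 2 libraries with 100 bp added to each width. Each library was also left out in turn, with the lone library of its genotype assumed to vary like the remaining pair. Alternatives chosen after the data were seen were lists limited to 12000 peaks, the presence of a chromosome Y peak as a covariate, and leaving out a library while keeping the region boundaries drawn from all 4. Plots were drawn with matplotlib 3.10.9.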

Results

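H3K4me3 was mapped in the brains of E12.5 mouse embryos, when neural progenitors divide and the first neurons form. The WT group had 2 libraries from controls without Cre. The dKO group had 2 libraries in which Lats1 and Lats2, the kinases of the Hippo pathway that restrain the transcriptional coactivators YAP and TAZ, were deleted with Nestin-Cre, a driver active in neural progenitors. The series title places the comparison in the question of how the Hippo pathway limits transcription and progenitor number. The lists held 19486 and 19331 peaks in WT replicates 1 and 2, and 18048 and 17367 peaks in dKO replicates 1 and 2. Peak widths ranged from 200 to 11119 bp in WT replicate 1, 205 to 11350 bp in WT replicate 2, 215 to 10415 bp in dKO replicate 1 and 210 to 7566 bp in dKO replicate 2. Read depth was unknown for all 4 libraries.

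The H3K4me3 domain on chromosome 2 from 117937631 to 117939938 (mm9) was wider in dKO. The WT libraries each had a single short peak in it, of 345 and 378 bp, and the dKO libraries had 2185 and 1988 bp under peaks. The means were 361.5 ± 23.3 bp in WT and 2086.5 ± 139 bp in dKO (SD, n = 2 each), a 5.77-fold difference. In dKO replicate 1 the mark formed a continuous peak from 117937633 to 117939817. In dKO replicate 2 it was called as 3 peaks, of 415, 1056 and 517 bp, with a further peak of 648 bp from 117940140 to 117940787, outside the region. All 4 libraries also had a peak just before the region, from 117937014 to 117937502 in WT replicate 1 and from 117937099 to 117937464 in dKO replicate 1. After centring, the log2 width change was 2.67 (SE 0.14, limma, adjusted p = 0.00809). The call was lost in 7 of 16 alternatives (adjusted p from 0.058 to 0.631), while the log2 change stayed between 2.38 and 2.68 in 6 of them, among these the fits without centring (2.53, adjusted p = 0.0756), with chromosome Y peaks as a covariate (2.67, 0.0631), without WT replicate 1 (2.64, 0.058) and without dKO replicate 2 (2.68, 0.0787). In the other, without dKO replicate 1, the region redrawn from the remaining lists ended at 117938074 and its change was 0.41 (adjusted p = 0.631), against 2.67 (0.00911) with the boundaries kept.

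**Figure D1:**
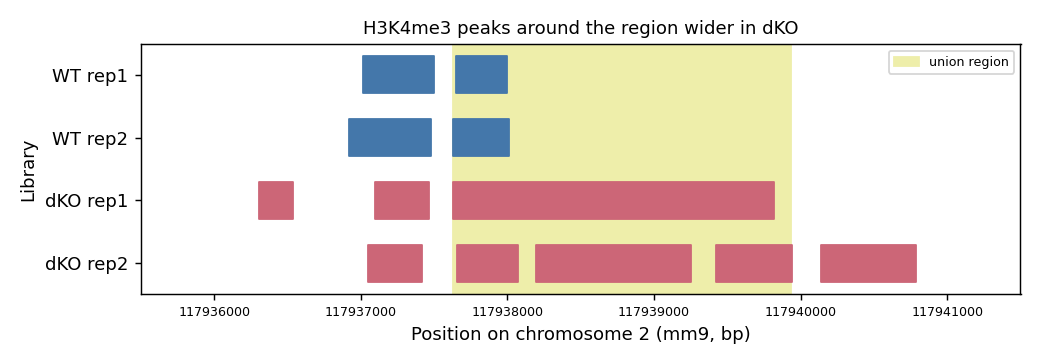
Peaks called in each library along chromosome 2 (mm9 position in bp on the horizontal axis, 1 row per library), with the union region from 117937631 to 117939938 shaded. Both WT libraries have a short peak at the left edge of the region, of 345 and 378 bp, while peaks cover 2185 bp in dKO replicate 1 and 1988 bp in dKO replicate 2.

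This was the only region of the 14943 with a peak in all 4 libraries to pass the limma threshold. At unadjusted p under 0.05, 422 regions had a wider and 725 a narrower mark in dKO, where chance alone gives about 747 in total. The total was 1147 for genotype. It was 478 for replicates 1 against replicates 2, and 608 for WT replicate 1 with dKO replicate 2 against the other 2 libraries. In the fits of the other pairings, any difference between genotypes counts as spread and can lower their totals. Those totals are therefore no measure of chance for the genotype total. Regions are not independent, so these totals carry no test. Without centring, the genotype counts were 45 wider and 1503 narrower, since the median log2 change before centring was -0.12 (0.023 after). The 5 regions next in order of p on the wider side did not pass, and were chosen after their values were seen. On chromosome 3 from 145310172 to 145313223 the widths were 1579 and 1519 bp in WT and 3052 and 2242 bp in dKO (log2 change 0.90, SE 0.12, adjusted p = 0.194). On chromosome 13 from 81769710 to 81772452 the means were 1213 ± 167 bp and 2043.5 ± 105 bp (SD, n = 2 each), and on chromosome 8 from 37675161 to 37677371 they were 1365 ± 32.5 bp and 1867 ± 160 bp. The domain on chromosome 11 from 35792369 to 35794506 measured 1509.5 ± 89.8 bp in WT and 2027.5 ± 156 bp in dKO. A much longer domain on chromosome 8, from 11001977 to 11010173, covered 5877 ± 447 bp in WT and 7491.5 ± 272 bp in dKO (log2 change 0.49, adjusted p = 0.244). Without dKO replicate 1 and with regions redrawn, the log2 change was 0.36 on chromosome 3 from 145310172, 0.19 on chromosome 8 from 11001977 and -0.054 on chromosome 13 from 81769710; with boundaries kept these were 0.74, 0.52 and 0.91.

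No region was called narrower in dKO by limma. The 5 regions with the smallest p in that direction each had an adjusted p of 0.184. On chromosome 4 from 155558637 to 155560750 the mark covered 2090 and 2105 bp in WT and 882 and 891 bp in dKO, a log2 change of -1.10 (SE 0.10). On chromosome 11 from 60021928 to 60024001 it covered 1963 ± 49.5 bp in WT and 944 ± 82.0 bp in dKO (SD, n = 2 each). The values on chromosome 10 from 79763714 to 79765438 were 1498.5 ± 111 bp and 525 ± 82.0 bp. Those on chromosome 5 from 137994317 to 137995435 were 1086 ± 35.4 bp and 357 ± 35.4 bp, and those on chromosome 15 from 98462670 to 98464175 were 1416 ± 77.8 bp and 590 ± 4.24 bp. Nearby peaks merged first moved the log2 change on chromosome 4 to -0.68, on chromosome 10 from -1.38 to -0.74 and on chromosome 15 from -1.12 to -0.45, while on chromosome 11 from 60021928 it went from -0.92 to -1.30 (limma, adjusted p = 0.0477). In redrawn regions it was -0.30 on chromosome 10 without WT replicate 2 and -0.55 on chromosome 11 without WT replicate 1. With peaks merged, 7 regions passed as narrower, the chromosome 11 region among them, and without dKO replicate 1, where the spread comes from the WT pair alone and the lone dKO library is assumed to vary like it, 49 did.

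**Figure D2:**
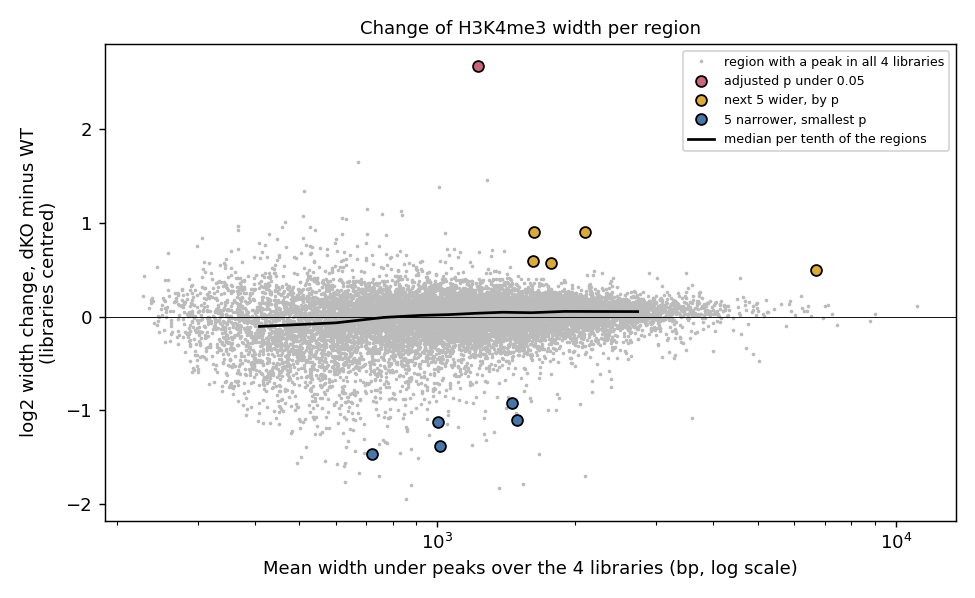
Centred log2 width change (dKO minus WT) of each of the 14943 regions with a peak in all 4 libraries, against the mean width under peaks in bp on a log axis; the line joins the medians of successive sets of 10% of the regions, ordered by mean log2 width. The chromosome 2 region lies apart at 2.67, and the medians run from -0.11 in the narrowest set to 0.053 in the widest (-0.25 to -0.089 before centring).

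The 10 broadest H3K4me3 domains were taken from the regions with a peak in all 4 libraries, so their presence in both genotypes was fixed by that choice. The widest lay on chromosome 7 from 86643765 to 86655114 and covered 11234.5 ± 163 bp in WT and 11000.5 ± 170 bp in dKO (SD, n = 2 each). A pair of neighbouring domains on chromosome 13 came next to each other, from 83857030 to 83866809 (9359 ± 137 bp in WT, 8690 ± 771 bp in dKO) and from 83866946 to 83874131 (7139.5 ± 55.9 bp and 7058.5 ± 72.8 bp). On chromosome 5 the domain from 111844877 to 111854569 covered 9364 ± 65.0 bp in WT and 8222.5 ± 640 bp in dKO, and the domain from 58105402 to 58112320 covered 6819.5 ± 141 bp and 6234 ± 478 bp. The domain on chromosome 1 from 42741047 to 42749991 covered 8027.5 ± 322 bp in WT and 6865.5 ± 829 bp in dKO. The remaining domains among the 10 widest were on chromosome 7 from 77500316 to 77507996 (7535 ± 185 and 6969.5 ± 347 bp), chromosome 2 from 17964228 to 17971854 (7088 ± 240 and 6956 ± 564 bp), chromosome 3 from 17689125 to 17696666 (7324 ± 122 and 6580 ± 457 bp), and the chromosome 8 domain from 11001977 to 11010173 given above. The last was the only domain of these 10 with a higher uncentred mean in dKO than in WT. Uncentred widths were lower in dKO over shared regions as a whole (medians 1161 and 1222 bp in WT, 1128 and 1033 bp in dKO). The lower dKO means are thus not particular to broad domains. None of the 10 passed the limma threshold, which was applied to centred widths.

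Most of the marked sites were shared by the genotypes. The 4 lists merged into 19712 union regions, and 14943 of them (75.8%) had a peak in all 4 libraries. A peak in both WT libraries and in neither dKO library was seen in 755 regions (3.83%), and the reverse in 27 (0.137%). The other ways of pairing the libraries gave 169 against 61 regions and 48 against 244. With each list limited to its 17367 highest peaks, the genotype counts were 295 and 96, and the other pairings gave 163 against 100 and 74 against 245. In limited lists a peak below the cut counts as absent, so these regions can hold a peak in the full lists of the other libraries. Peaks within 1000 bp merged first gave 433 and 15 for the genotypes, and lists of 12000 peaks, a limit chosen after the data were seen, gave 155 and 111.

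Regions marked only in WT were short and weak. Their median peak width was 300 bp, against 1136 bp in the regions of all 4 libraries, and their median score stood at percentile 10.1 of the WT replicate 1 list and 11.5 of the WT replicate 2 list. This was not particular to them. Over all combinations lacking a library, medians ran from 248.5 bp (dKO replicate 2 alone) to 366 bp (all but dKO replicate 2). The median best score of these 2 combinations was 34 and 98, against 515 in regions of all 4 libraries. The widest region marked only in WT was on chromosome 2 from 158437756 to 158438997, with 1135 and 1242 bp in WT replicates 1 and 2. It was followed by regions on chromosome 6 from 126113289 to 126114370 (996 and 1030 bp), chromosome 9 from 41393682 to 41395279 (1375 and 898 bp), chromosome 12 from 89962998 to 89964194 (776 and 1106 bp) and chromosome 13 from 106234447 to 106235255 (765 and 809 bp). The other 5 named regions were on chromosome 2 from 57550996 to 57551833 and from 50995638 to 50996836, chromosome 9 from 58051142 to 58052129, chromosome 4 from 128904312 to 128905103 and chromosome 11 from 114588305 to 114589077, where the smaller of the 2 WT widths was 764, 676, 757, 710 and 651 bp in that order.

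Regions marked only in dKO were as short, with a median peak width of 294.5 bp and a median score at percentile 7.04 of the dKO replicate 1 list and 7.0 of the dKO replicate 2 list. The widest lay on chromosome 15 from 79844107 to 79844753, with 638 and 611 bp in dKO replicates 1 and 2, and the next on chromosome 13 from 100215955 to 100216668 (526 and 615 bp). On chromosome 5, regions from 93113044 to 93113592 (549 and 479 bp) and from 93239306 to 93239917 (570 and 474 bp) came after these. The region on chromosome 11 from 116195626 to 116196160 (535 and 423 bp) followed. The smaller of the 2 dKO widths was 329 bp on chromosome 2 from 118380115 to 118380493, 328 bp on chromosome 2 from 13498649 to 13499012, 324 bp on chromosome 1 from 135995583 to 135996243, 305 bp on chromosome 11 from 107776057 to 107776378 and 294 bp on chromosome 14 from 57483768 to 57484069. Of the 10 named dKO-only regions, 4 stayed so with peaks within 1000 bp merged, 2 with peaks under 500 bp left out and 0 with lists of 12000 peaks, and of the 10 named WT-only regions 5, 8 and 0 did. The cut at 500 bp removes most of the named dKO-only regions by their width alone. Peaks of low score are the first to fall outside lists of 12000. The counts for these 2 settings therefore do not measure stability or compare the genotypes. Of all such regions, 267 of the 755 in WT (35.4%) and 10 of the 27 in dKO (37.0%) lay within 1000 bp of a region with a peak in all 4 libraries. Presence in 2 libraries against absence in 2 carries no p, and absence of a peak means only that none passed the caller's threshold.

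**Figure D3:**
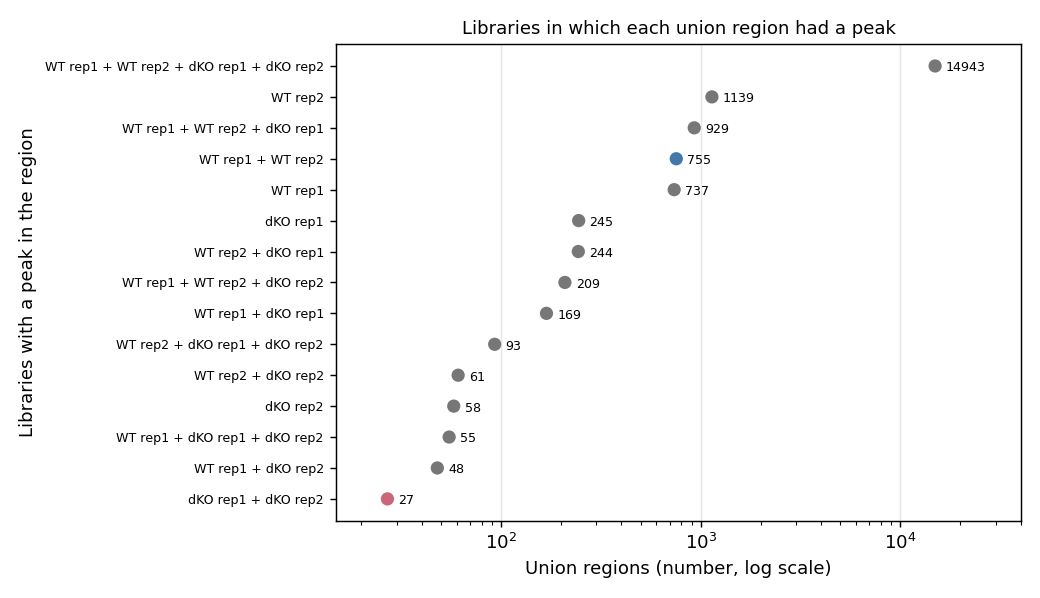
Number of union regions (log axis) for each combination of libraries with a peak in the region, ordered by number. The combination of all 4 libraries holds 14943 regions, the 2 WT libraries alone 755 and the 2 dKO libraries alone 27, the fewest of any combination.

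The dKO libraries had fewer peaks and less sequence under peaks, with groups that did not overlap; the exact permutation test used cannot give a p below 0.3333 with 2 libraries against 2. The mean number of peaks was 19408.5 ± 110 in WT and 17707.5 ± 482 in dKO (SD, n = 2 each), 8.76% lower (exact permutation p = 0.3333). Peaks covered 20.3 and 21.4 Mb in the WT libraries and 19.3 and 17.3 Mb in the dKO libraries, 12.1% lower on average (exact permutation p = 0.3333). The difference in sequence was -2511181 bp, and -1511736 bp without dKO replicate 2. The difference in number was -1701 peaks, and -1094 with peaks within 1000 bp merged. The deposited scores, on a scale the labels do not name, had a median of 338.5 and 324 in the WT lists and 312 and 230 in the dKO lists, and a maximum of 1444 and 1406 in WT and 1162 and 870 in dKO, lowest in dKO replicate 2. The median peak width was 920 and 984 bp in WT and 960 and 888 bp in dKO, so the groups overlapped (exact permutation p = 0.6667), and the sign of the difference turned when WT replicate 2 or dKO replicate 2 was left out (4 and 8 bp higher in dKO). The difference was -28 bp with all libraries, -105 bp with lists of equal length, -70 bp with nearby peaks merged, -60 bp without WT replicate 1 and -64 bp without dKO replicate 1. Of the union regions with a peak in either library of a pair, the share with a peak in both was highest for dKO replicates 1 and 2 (88.5%), followed by WT replicate 1 with dKO replicate 1 (87.2%), WT replicates 1 and 2 (86.9%) and WT replicate 2 with dKO replicate 1 (85.9%). It was lowest for WT replicate 2 and dKO replicate 2 (82.5%). The order differed for shared base pairs as a fraction of the base pairs in either list. That fraction was highest for the WT replicates (0.8194), then WT replicate 1 with dKO replicate 1 (0.8179) and the dKO replicates (0.8108). Chromosome X held 668 and 669 peaks in WT and 612 and 548 in dKO. Chromosome Y held 2 peaks in WT replicate 1, 3 in dKO replicate 2 and 0 in WT replicate 2 and dKO replicate 1, so that each genotype had 1 library with and 1 without, too few for a test within either kind.

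**Figure D4:**
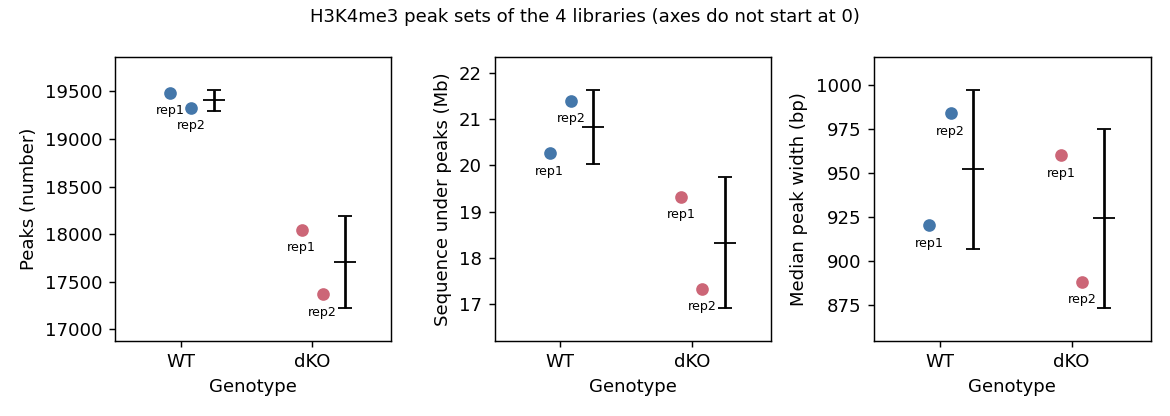
Number of peaks, sequence under peaks in Mb and median peak width in bp of each library (points), with the mean and SD of each genotype (bars, n = 2); the axes do not start at 0. WT libraries lie above dKO libraries for peaks (19331 and 19486 against 17367 and 18048) and sequence, and the genotypes overlap for median width.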

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

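Limits of 12000 peaks, the chromosome Y covariate and kept region boundaries were chosen after the data were seen. The number of peaks and the base pairs under peaks stayed lower in dKO under every alternative run (-1094 to -2041.5 peaks, -1511736 to -3510626 bp); limiting lists to equal length leaves no difference in number to measure. The difference in median peak width ranged from -64 to 8 bp with a library left out, at 4 bp without WT replicate 2 and 8 bp without dKO replicate 2, and was -105 bp with equal lists and -70 bp merged. Regions only in dKO numbered 27, but 96 with lists of equal length, 111 with 12000 peaks, 15 with peaks within 1000 bp merged, and 89 to 281 with a library left out, where presence or absence rests on a single library of the genotype left with 1. Regions only in WT numbered 755, but 295 with equal lists, 155 with 12000 peaks, 433 merged, 463 without peaks under 500 bp, and 966 to 2011 with a library left out. In limited lists, for either genotype, a peak below the cut counts as absent though the full list holds it. The count of wider regions was 1, and 0 without centring, with the chromosome Y covariate and over regions in at least 2 libraries. It was 0 to 1 with a library left out; with boundaries kept it was 3 without dKO replicate 1 and 0 without dKO replicate 2. Those 3 were the chromosome 2 region, chromosome 8 from 11001977 and chromosome 1 from 82280026 to 82284240. The count of narrower regions was 0, but 7 merged, 0 to 49 with a library left out and 106 without dKO replicate 1 with boundaries kept; without that library the spread comes from the WT pair alone. The chromosome 2 call held in 9 of 16 alternatives (log2 1.96 to 2.74, adjusted p 0.00415 to 0.0357), and in 6 of the other 7 the change was 2.38 to 2.68. Without dKO replicate 1 its change was 0.41 in redrawn regions and 2.67 with boundaries kept (adjusted p = 0.00911), so the redrawing made the difference. The same holds for chromosome 13 from 81769710, at -0.054 and 0.91 (-0.054 to 1.08 over the libraries left out). Of the 176 alternative values of the 11 named width changes, 159 kept direction and side of the threshold, some with another size, 7 dropped below it, 9 rose past it and 1 reversed. Only the chromosome 2 region was past the threshold in the main fit. For the others, keeping its side meant only that they still did not pass. The chromosome 10 change counts as kept though it went from -1.38 to -0.30 without WT replicate 2. Most values that rose past the threshold came from fits without dKO replicate 1. The tally is therefore no measure of stability. Where no cause is given, the cause was not tested. With the replicate number as a replicate block there was 1 wider region (adjusted p = 0.00415) and 0 narrower; same-numbered libraries did not deviate together (correlation over regions -0.059). The 27 gene lists were not run, for lack of mm9 annotation here, and unknown depth limits every comparison.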

Other observations

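The limit of 4000 bp for broad domains was chosen only after the results it concerns were seen. So were the limit of 12000 peaks and the use of list length, library pairing and peak strength to weigh explanations. Lists of equal length were themselves an alternative set before the data were examined. Among the regions with a peak in all 4 libraries, 120 had at least 4000 bp under peaks in at least 1 library and 56 in all 4. There were 95 such domains in WT replicate 1, 105 in WT replicate 2, 79 in dKO replicate 1 and 62 in dKO replicate 2. In 11 domains both WT libraries and neither dKO library reached 4000 bp, and in 0 the reverse. The 3 with the largest difference in mean width were on chromosome 3 from 88010425 to 88016726 (6089 ± 204 bp in WT, 3964.5 ± 40.3 bp in dKO; SD, n = 2 each), chromosome 11 from 84334211 to 84340348 (5059 ± 1151 and 2142.5 ± 196 bp) and chromosome 3 from 88336239 to 88341046 (4691 ± 158 and 3295.5 ± 326 bp). The other pairings gave 5 domains for WT replicate 2 with dKO replicate 1, on chromosome 1 from 135027162, chromosome 10 from 41994301 and from 84218131, chromosome 14 from 118632711 and chromosome 2 from 152220258. They gave 1 for WT replicate 2 with dKO replicate 2, on chromosome 5 from 137040773, and 0 for the remaining pairings. These counts carry no test and are in uncentred widths, which were lower in dKO over shared regions as a whole (medians 1161 and 1222 bp in WT, 1128 and 1033 bp in dKO).

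Regions with a peak in both WT libraries and neither dKO library outnumbered the reverse, 755 to 27. With equal lists, where a peak below the cut counts as absent, the ratio was 3.07 (95% counting interval 2.44 to 3.87). With 12000 peaks it was 1.40, and 1.67 for WT replicate 2 with dKO replicate 1 against the other 2 libraries. Peaks of low score are the first to fall outside that limit, so this ratio says little about the 755 regions. The interval of the equal lists leaves out the spread between libraries, and with these lists a pairing across genotypes gave a ratio of 3.31. That pairing set WT replicate 1 with dKO replicate 2, the 2 libraries with chromosome Y peaks, against the other 2. Its ratio cannot be separated from a difference that follows those peaks. Unequal list lengths cannot be told apart from library differences that do not follow genotype, and both remain open. Weak peaks near the calling floor also remain open, with the WT-only regions at a median score percentile of at most 11.5 in the WT lists. A loss of the mark at weak sites in dKO is an untested possibility beside these, and the mix of cell types was not examined.

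The chromosome 2 region from 117937631 to 117939938 may be a site where H3K4me3 in dKO brain tissue reaches beyond its WT extent. The mix of cell types in the tissue was not examined, so spread of the mark within cells cannot be inferred. A WT domain broken into several called peaks was argued against, since merging peaks within 1000 bp left a log2 change of 1.96 (SE 0.11, adjusted p = 0.0357). A linked segment from another strain, a concern in mice of mixed background, stays open. The 21 neighbours within 1 Mb with a peak in all 4 libraries had a median absolute log2 change of 0.078. That was at percentile 8.21 of the regions with 5 or more neighbours, where the typical value was 0.12. Their median cannot decide the question, since such a segment need not change most widths in it. A dKO-only region on chromosome 2 from 118380115 to 118380493 lay within 1 Mb but did not enter the median. A variant within the region itself and the genotype effect stay open, untested, and the adjusted p ranged from 0.00415 to 0.631 over 16 alternatives, the highest without dKO replicate 1.

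Relative to the median of each library, narrow regions tended to be narrower and wide regions slightly wider in dKO, with a median log2 change of -0.11 in the narrowest 10% of regions and 0.053 in the widest 10%. Before centring both medians were lower in dKO, -0.25 and -0.089, so the sign in wide regions comes from the centring and only the difference between narrow and wide regions is independent of it. The rank correlation of width change with mean width was 0.19 across regions, which are not independent replicates. Differences between libraries within a genotype cannot be told apart from this, as the same correlation reached a size of 0.157 between the dKO replicates, too close to the value between genotypes to decide. Between the WT replicates it was 0.039. From the narrowest to the widest 10%, the median for dKO replicate 2 minus dKO replicate 1 ran from -0.09 to 0.062. For WT replicate 1 minus WT replicate 2 it ran from -0.02 to 0.027. In each pair, the library with less sequence under peaks thus had the same tilt as dKO. Whether the tilt follows the amount of sequence was not tested. A genotype effect stays open, untested.

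A further hypothesis was that neighbouring regions widen together in dKO. Of the 53 regions wider at unadjusted p under 0.01, 2 lay within 100000 bp of another of them, on chromosome 13 from 24892934 to 24895637 and from 24922609 to 24925103. In 10000 random draws of as many regions the median was 0 and the 95th percentile 2 (one-sided permutation p = 0.2592), so the test does not decide the question.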
